A study of Mus musculus with 10 samples.

How the data were processed

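Gene expression was measured by RNA sequencing in kidneys of C57BL/6 mice, 5 libraries from animals at 400 m (control) and 5 from animals at 4200 m (hypoxia), each group for 30 days. Groups were taken from the treatment label and replicate numbers from the sample titles. The labels' protocols describe extraction with Trizol and libraries made with an Illumina TruSeq kit, and name the retina as the tissue removed, whereas every sample is labelled kidney. Retina markers summed to 7.82 ± 1.40 FPKM in controls and 6.50 ± 1.72 FPKM in hypoxia (SD, n = 5), against 3747 FPKM for proximal tubule markers in controls.

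The authors deposited 1 table of FPKM values for 55952 genes, with gene names, coordinates, lengths and biotypes. The deposited table also gives each gene's length in bases, an other unit used here only to recover reads. Reads were aligned with HISAT2 2.0.5, per the submitters' processing notes, which also list the human build hg38. The gene identifiers are those of the mouse, and of the 55227 found in a GRCm38 annotation 99.4% had identical start and end coordinates, so coordinates are given as GRCm38. The tool that counted reads, its treatment of strand and of reads with several matches, and the annotation release are not given in the sources used here. A further 465 loci had no gene name.

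FPKM times gene length fell on whole multiples of 1 step per library for 100% of the values (tolerance 0.05), so whole reads were recovered, 16561672 to 17845464 per library. The library size implied by the step was 0.949 to 1.10 times the sum of those reads, which means that the authors' FPKM had been divided by a library size other than that sum. Floors given in FPKM correspond to 3 reads and cover counting error only. Some genes with near-identical copies were listed near 0, for example Gapdh at a mean of 1.53 FPKM in controls, and reads of such genes were probably lost or shared in the counting. Gapdh is 1 of the 20 tested members of the glycolysis list and did not pass the gene test (adjusted p = 0.635).

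Values were used as deposited, without further scaling. Genes with a mean of at least 0.5 FPKM over the 10 samples (15264) were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are hypoxia minus control. Gene lists fixed before the data were examined (47, of which 44 had at least 4 tested members) were tested with camera at a preset correlation of 0.01, adjusted over the 44 lists, and again with an estimated correlation and with fry. The lists of retina, skeletal muscle and RNA quality genes had too few tested members. Summed FPKM of the 16 cell type and tissue lists was compared with an exact two-sided permutation test over 252 regroupings. Counts adjusted over the list alone repeat the Benjamini-Hochberg adjustment within each list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

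Named genes followed a rule fixed before the data were examined. It takes the 10 largest increases and the 10 largest decreases among protein-coding genes past the threshold with a mean of at least 2 FPKM and no overlap of the groups, up to 4 members of each list with the smallest p among those past the threshold (or the 2 most abundant members where none passes), and always Hif1a, Epas1, Epo, Vegfa, Car9, Havcr1 and Lcn2. Genes named outside this rule are said to have been chosen after their values were seen. A few genes that the rule takes are not reported here.

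The gene test was tried on simulated libraries with 15300 tested genes. It recovered 59.1% of 66 genes changed by 0.5 on the log2 scale and 88.1% of 67 genes changed by 1, with 7 false calls, and made 5 calls where nothing had been changed. The simulation gave every gene the same dispersion of 0.01 in both groups. The real hypoxia libraries varied more than the controls, so these rates need not hold for the real comparison. Alternatives planned before the data were examined covered scaling, pseudocount, filters, error model, an exact rank-sum test, a replicate block, stricter thresholds and the omission of each library in turn. A fit without hypoxia replicates 4 and 5 and limma voom on the recovered reads were added after seeing the data. No 2 libraries were alike within sampling noise, so all 10 were counted as separate samples. GC content was taken from GRCm38 transcripts for 14926 of the 15264 tested genes. Y-linked Ddx3y was at 12.2 to 16.3 FPKM in all libraries and Xist at most at 0.0188 FPKM.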

Results

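Kidney RNA of C57BL/6 mice, a widely used inbred strain, was compared between animals kept at 400 m (control, 5 libraries) and at 4200 m (hypoxia, 5 libraries) for 30 days. Expression was measured by bulk RNA sequencing and was deposited as FPKM, the fragments of a gene scaled to its length and to the size of the library. Whole reads could be recovered from these values, and the 10 libraries held between 16561672 and 17845464 reads assigned to genes. A gene of 1 kb would have to reach 0.165 to 0.183 FPKM, depending on the library, to rest on 3 reads. The labels list separate samples without stating that each came from its own mouse, so p-values measure the spread between these samples. Altitude and site of housing could not be separated, because each group was kept at its own altitude.

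The libraries of the 2 groups separated, and 2 hypoxia libraries also differed from the other 3. Control libraries correlated with their own group at a median r of 0.979 to 0.982 across genes, and hypoxia replicates 1 to 3 at 0.968 to 0.971. Hypoxia replicate 4 reached 0.959 and hypoxia replicate 5 only 0.853. Hypoxia replicate 5 held high levels of genes of B cells and of digestive enzymes of the pancreas, for example Cd79a at 106 FPKM and Ctrb1 at 15.4 FPKM, against at most 0.642 and 0.0680 FPKM in the controls and hypoxia replicates 1 to 3. Hypoxia replicate 4 held steroid synthesis genes of the adrenal gland, with Cyp21a1 at 246 FPKM and Star at 218 FPKM, and fat tissue genes, with Cfd at 508 FPKM against 99.8 FPKM in the highest control. Of these genes, all but Cyp21a1 were chosen after their values were seen. Because of these 2 libraries, the main counts are also given without them, an alternative chosen after seeing the data.

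**Figure D1:**
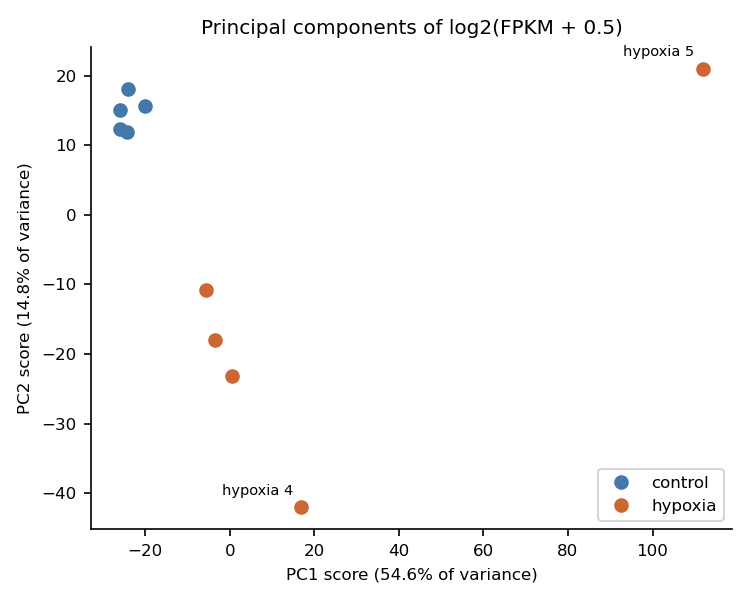
Scores of the 10 libraries on the first principal component (54.6% of the variance) and the second (14.8%), from log2(FPKM + 0.5), with control and hypoxia libraries as separate colours. Hypoxia replicate 5 lies at 111.9 on the first component, and no other library exceeds 16.9.

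**Figure D2:**
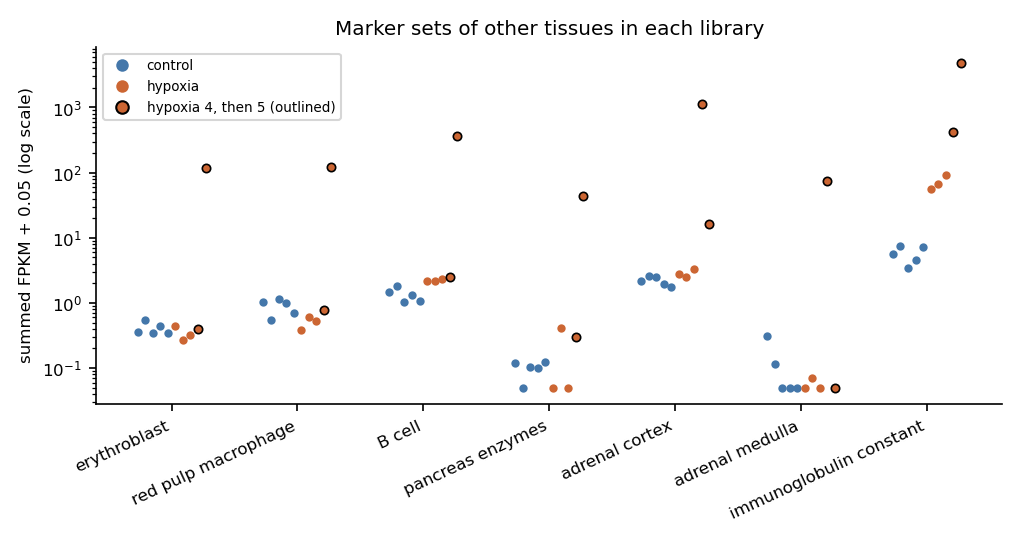
Summed FPKM of 7 marker sets of other tissues in each library, on a log axis after adding 0.05, with each point 1 library and hypoxia replicates 4 and 5 outlined in that order. Erythroblast, red pulp macrophage, B cell and pancreas sets are highest in hypoxia replicate 5, and both adrenal sets in hypoxia replicate 4.

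The series asked how the kidney transcriptome changed at high altitude. The genes with large changes named here are protein-coding genes past the threshold, with a mean of at least 2 FPKM and no overlap between the groups. Slc22a7, an organic anion transporter, fell from 141.8 ± 24.6 FPKM in controls to 6.12 ± 5.96 FPKM in hypoxia (SD, n = 5 each), and Slco1a1, an organic anion transporting polypeptide, fell from 55.3 ± 17.3 to 5.50 ± 3.25 FPKM. Cyp7b1, an oxysterol hydroxylase, fell from 95.2 ± 21.4 to 13.8 ± 3.57 FPKM, and Acsm3, a medium-chain acyl-CoA synthetase, from 162.5 ± 22.6 to 39.0 ± 27.3 FPKM. Among the largest increases, Slc7a12, an amino acid transporter, rose from 5.21 ± 2.68 to 56.5 ± 21.1 FPKM, Serpina1a, a secreted protease inhibitor, from 10.98 ± 2.63 to 56.3 ± 13.9 FPKM, and Prlr, the prolactin receptor, from 1.38 ± 0.448 to 8.28 ± 1.87 FPKM. Hpd, an enzyme of tyrosine breakdown, rose from 9.17 ± 3.93 to 41.1 ± 13.1 FPKM. In each of these 8 genes the 5 hypoxia values lay entirely outside the range of the 5 control values.

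On the log2(FPKM + 0.5) scale, which understates the change of low genes, the log2 fold change of Slc22a7 was -4.80 (SE 0.455, limma adjusted p = 0.000348), that of Slco1a1 -3.35 (SE 0.371, adjusted p = 0.000880) and that of Cyp7b1 -2.74 (SE 0.204, adjusted p = 8.04e-05). It was 3.38 for Slc7a12 (SE 0.317, adjusted p = 0.000348), 2.30 for Serpina1a (SE 0.198, adjusted p = 0.000224) and 2.22 for Prlr (SE 0.185, adjusted p = 0.000195). In the files' mouse coordinates, which match GRCm38, Slc22a7 (ENSMUSG00000067144) lies on chromosome 17 from 46432183 to 46438457, Cyp7b1 (ENSMUSG00000039519) on chromosome 3 from 18071950 to 18243338, Slc7a12 (ENSMUSG00000039710) on chromosome 3 from 14480697 to 14505830 and Prlr (ENSMUSG00000005268) on chromosome 15 from 10177238 to 10349180. The other genes with the largest decreases under the same rule were Sec14l3, Akr1c18, Ttr, Slc9a8, mt-Atp8 and Ces2b, with log2 fold changes from -3.04 for Sec14l3 to -2.07 for Ces2b. The other large increases were Jchain, S100a8, Ugt1a2, Abcb1b, C4b and Nnat, from 3.89 for Jchain to 2.05 for Nnat. Without hypoxia replicates 4 and 5 the log2 fold change was 2.51 for Jchain, 2.34 for S100a8, 1.49 for C4b and 1.41 for Nnat. Jchain and S100a8 were highest in hypoxia replicate 5, at 126.6 and 101.2 FPKM, and Nnat in hypoxia replicate 4, at 17.6 FPKM. The calls of Jchain, S100a8 and mt-Atp8 were lost in 1, 7 and 2 of the 10 fits without 1 library, with adjusted p up to 0.0521 (without control replicate 2), 0.0949 (without control replicate 1) and 0.0638 (without control replicate 2).

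**Figure D3:**
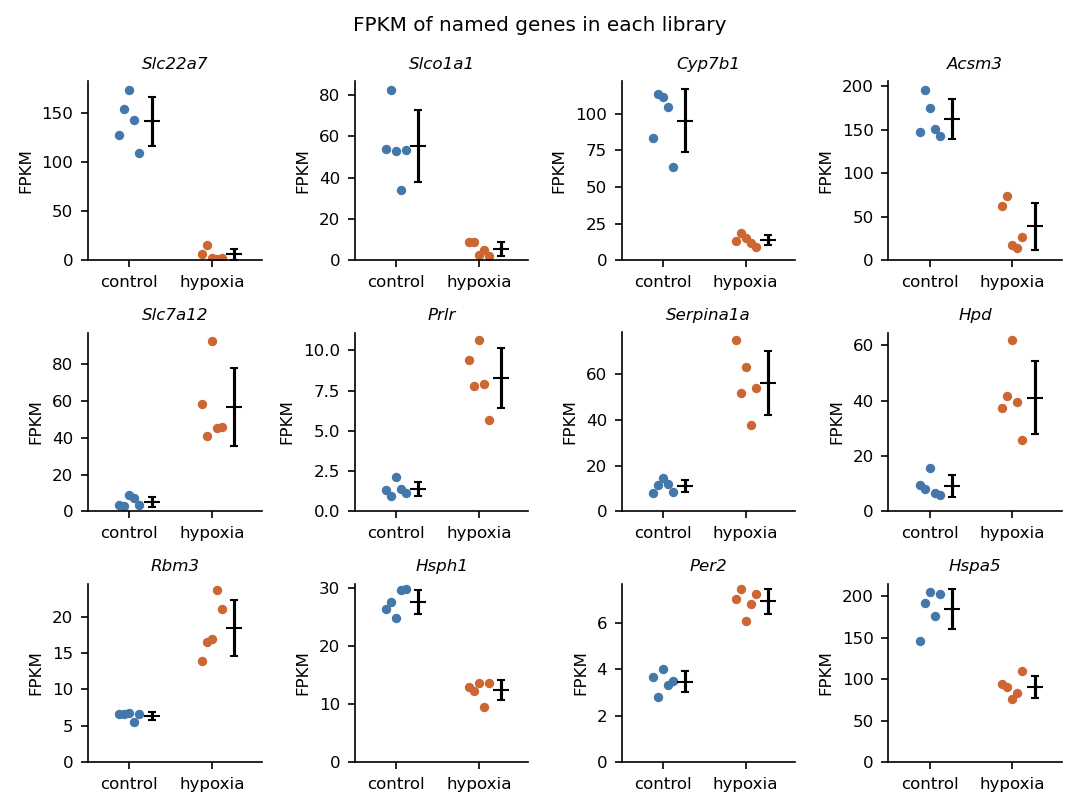
FPKM of 12 named genes in each of the 5 control and 5 hypoxia libraries, with each point 1 library and the bar beside it the mean ± SD (n = 5). In all 12 panels the 2 groups do not overlap, with Slc22a7 at a mean of 141.8 FPKM in controls and 6.12 FPKM in hypoxia.

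Across the transcriptome, 1748 of 15264 tested genes passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), 559 higher and 1189 lower in hypoxia. Of the tested genes, 2170 (14.2%) had no overlap between the 2 groups, against 0.794% by chance. When the values were rescaled without the most abundant genes, 961 genes were higher and 780 lower, so the excess of lower genes depended on the scaling. Without hypoxia replicates 4 and 5, 1808 of 14724 genes passed, 667 higher and 1141 lower, of which 1301 were among the 1748 and changed in the same direction. The count was 824 without control replicate 1, 864 without control replicate 2, 947 without control replicate 3, 1016 without control replicate 5, 1053 without hypoxia replicate 4 and 2724 without hypoxia replicate 5. An exact rank-sum test passed 0 genes, with 3975 at an unadjusted p under 0.05 against 4451 with limma.

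The series used HIF-1α, the oxygen-regulated subunit of a hypoxia-inducible transcription factor, as a check of its hypoxia model. Hif1a was at 17.8 ± 1.46 FPKM in controls and 21.1 ± 2.75 FPKM in hypoxia (SD, n = 5 each), a log2 fold change of 0.24 (SE 0.0956, limma adjusted p = 0.133) that did not pass the threshold. Taken as a single gene, its unadjusted limma p was 0.0324, so the outcome depends on the adjustment over all tested genes. The values of the 2 groups overlapped. Epas1, which encodes HIF-2α, had a log2 fold change of 0.10 (SE 0.0867, adjusted p = 0.472) and Vegfa, a vascular growth factor induced by HIF, one of 0.0040 (SE 0.166, adjusted p = 0.990). Epo, the erythropoietin gene, rested on 1 to 8 reads per control library and 0 to 5 per hypoxia library. It was below the filter and not tested, and a small difference was not detectable at this depth. Of 12 tested genes of the HIF pathway itself, 0 passed (limma, also 0 adjusted over the list alone).

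HIF target genes went in both directions. Car9, a carbonic anhydrase, rose from 3.27 ± 0.720 to 8.14 ± 3.20 FPKM (log2 fold change 1.15, adjusted p = 0.0131), Pdk1, a kinase that inhibits pyruvate dehydrogenase, from 6.47 ± 0.517 to 9.92 ± 0.642 FPKM (0.58, adjusted p = 0.00140) and Bnip3, a mitophagy receptor, from 39.1 ± 2.57 to 60.5 ± 8.11 FPKM (0.61, adjusted p = 0.00603). Higd1a, a mitochondrial protein, fell from 14.3 ± 0.648 to 6.804 ± 1.21 FPKM (-1.03, adjusted p = 0.000772), P4ha1, a collagen prolyl hydroxylase, from 20.2 ± 1.65 to 10.8 ± 1.61 FPKM (-0.87, adjusted p = 0.00117), and Ldha, lactate dehydrogenase A, from 218.0 ± 13.4 to 148.1 ± 18.0 FPKM (-0.56, adjusted p = 0.00793). Of 26 tested targets, 3 were higher and 6 lower, and 6 and 6 adjusted over the list alone. Neither list shifted as a set, with camera adjusted p = 0.909 for the targets and 0.946 for the pathway.

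Energy metabolism, the subject named by the series, had lower medians in several lists, none of which held as a set with an estimated correlation. Complex I subunits of the respiratory chain had a median log2 fold change of -0.35, with 14 of 35 members lower and 0 higher (23 lower adjusted over the list alone), and subunits of complexes III and IV and ATP synthase one of -0.37, with 9 of 35 lower and 0 higher (27 lower adjusted over the list alone). Ndufa1, a complex I subunit, fell from 216.3 ± 36.9 to 96.1 ± 24.4 FPKM (SD, n = 5 each), Ndufs6 from 82.3 ± 11.3 to 37.5 ± 10.4 FPKM, and Cycs, cytochrome c, from 85.9 ± 11.6 to 44.97 ± 9.54 FPKM. In fatty acid oxidation 7 of 28 genes were lower (10 adjusted over the list alone, median -0.27), among them Acadm, medium-chain acyl-CoA dehydrogenase, which fell from 288.9 ± 32.4 to 129.5 ± 34.0 FPKM. In the citric acid cycle 4 of 23 were lower (12 adjusted over the list alone, median -0.29), among them Pdhx, a component of the pyruvate dehydrogenase complex, at -0.35. In glycolysis 5 of 20 were lower (6 adjusted over the list alone, median -0.27), with Pklr, a pyruvate kinase, at -0.68, Pgam1 at -0.69 and Eno1 at -0.47.

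These 5 lists passed camera with its preset correlation, at adjusted p = 3.3e-10 for complex I and for complexes III to V, 3.31e-05 for fatty acid oxidation, 3.54e-05 for the citric acid cycle and 0.00105 for glycolysis. None of the 5 held with an estimated correlation, where the adjusted p was 0.862 for complex I, for complexes III to V and for glycolysis, and 0.984 for fatty acid oxidation and the citric acid cycle. Without hypoxia replicates 4 and 5 the camera calls of the 5 lists held, with medians of -0.23 for complex I and -0.28 for complexes III to V. The citric acid cycle genes were near the threshold, and Pdhx, Idh3a and Cs lost their calls in 5, 8 and 9 of the 10 fits without 1 library. Their adjusted p was highest without control replicate 1, at 0.0790, 0.112 and 0.116. Proximal tubule markers, which come from a nephron segment rich in mitochondria, had a median of -0.16 with 0 of 12 past the threshold (camera adjusted p = 0.227). The median was 0.054 without hypoxia replicates 4 and 5 (camera adjusted p = 0.960). Distal convoluted tubule markers had a median of -0.30, and -0.24 without those 2 libraries (camera adjusted p = 0.227 and 0.196). Thick ascending limb markers had one of -0.075, and 0.085 without them (camera adjusted p = 0.518 and 0.960).

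Other energy lists did not pass camera. Gluconeogenesis had 0 of 12 genes past the threshold (camera adjusted p = 0.204), with Pck1 at 808.8 ± 209.2 FPKM in controls and 530.2 ± 185.2 FPKM in hypoxia (adjusted p = 0.130). Of 13 genes of the mitochondrial genome, 3 were lower, mt-Co2, mt-Atp6 and mt-Atp8 (camera adjusted p = 0.539). The last 2 overlap in part, so that some of their reads cannot be told apart, and mt-Atp8 rested on 2 to 13 reads per hypoxia library. The list median was -0.029, and 0.057 without hypoxia replicates 4 and 5. Reads of all mitochondrial genes made up 8.68 to 9.72% of the total in controls. Their share was 10.1 to 12.3% in hypoxia replicates 1 to 4 and 8.50% in hypoxia replicate 5. Among targets of PPARα, a regulator of lipid use, Cyp4a14 rose from 43.7 ± 12.1 to 160.0 ± 61.1 FPKM (log2 fold change 1.82, adjusted p = 0.00218) and Acot3 from 3.46 ± 0.505 to 6.77 ± 0.733 FPKM, while 2 of the 21 tested members were lower, among them Ehhadh (camera adjusted p = 0.518). The call of Ehhadh was lost without hypoxia replicates 4 and 5 (adjusted p = 0.131, log2 fold change -0.50 against -0.73 with all libraries), as was that of mt-Atp6 (adjusted p = 0.127, -1.16 against -1.45), and these 2 genes and mt-Co2 each lost it in 6 to 9 of the 10 fits without 1 library.

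**Figure D4:**
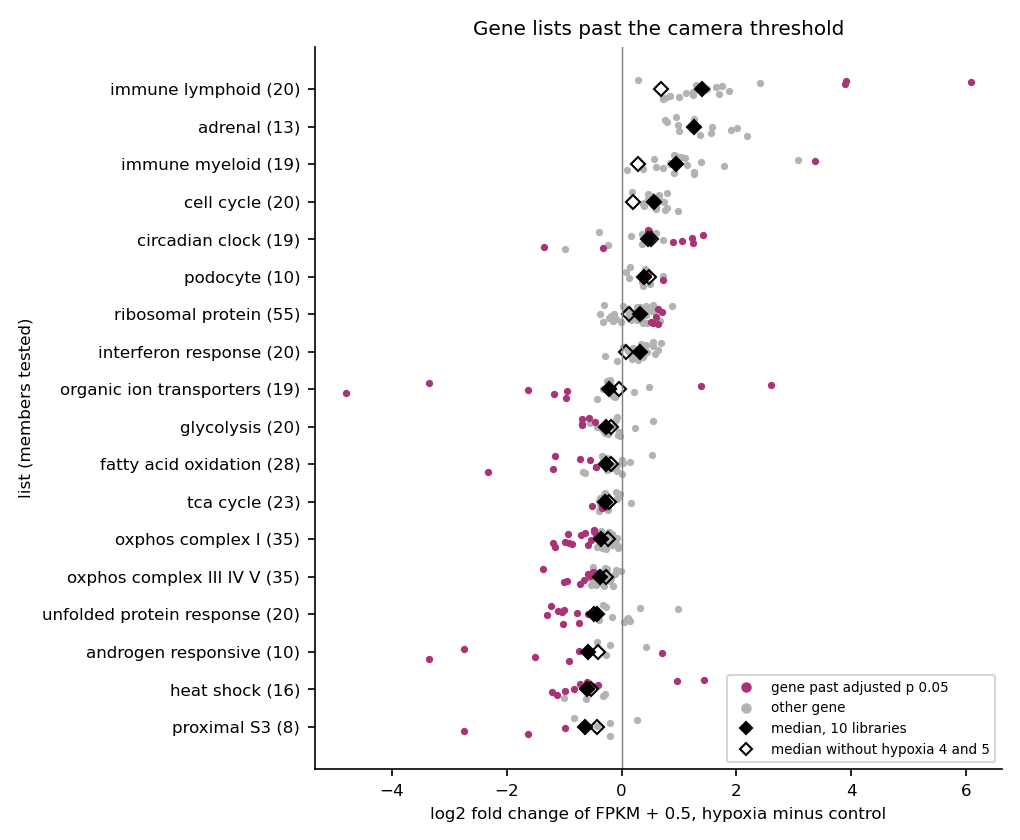
Log2 fold changes (hypoxia minus control) of the members of the 18 gene lists that passed camera, with each point 1 gene, coloured where it passed an adjusted p of 0.05, and diamonds for the list median over 10 libraries (filled) and without hypoxia replicates 4 and 5 (open). The medians range from -0.63 for late proximal tubule markers to 1.41 for lymphoid genes.

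Chaperone genes formed another group that was lower in hypoxia. Of 16 heat shock genes, 10 were lower and 2 higher (14 and 2 adjusted over the list alone), with Hsph1 falling from 27.6 ± 2.11 to 12.4 ± 1.74 FPKM, Dnaja1 from 47.5 ± 3.96 to 20.4 ± 4.10 FPKM and Hsp90aa1 from 154.9 ± 13.5 to 78.4 ± 9.44 FPKM (SD, n = 5 each). The 2 higher members, Rbm3 and Cirbp, encode RNA-binding proteins known for induction by cold, and Rbm3 rose from 6.41 ± 0.523 to 18.4 ± 3.88 FPKM and Cirbp, named after its values were seen, from 8.29 ± 0.791 to 16.9 ± 3.34 FPKM. Of 20 genes of the unfolded protein response, 10 were lower and 0 higher (11 lower and 1 higher adjusted over the list alone), including Hspa5, the main chaperone of the endoplasmic reticulum, which fell from 184.4 ± 24.3 to 91.0 ± 12.9 FPKM, and Calr, calreticulin, from 302.5 ± 34.5 to 147.1 ± 6.34 FPKM. Camera gave adjusted p = 9.53e-06 for heat shock and 3.54e-05 for the unfolded protein response. With an estimated correlation the adjusted p was 0.0461 for heat shock, the only list that held, and 0.359 for the unfolded protein response. Without hypoxia replicates 4 and 5 the heat shock call with an estimated correlation was lost as well (adjusted p = 0.0791), at a median of -0.53 against -0.60 with all libraries.

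Of 19 tested clock genes, 9 were higher and 2 lower (13 and 3 adjusted over the list alone, camera adjusted p = 0.000369, adjusted p = 0.193 with an estimated correlation). Per1 rose from 4.87 ± 2.15 to 11.7 ± 2.04 FPKM, Per2 from 3.48 ± 0.446 to 6.93 ± 0.534 FPKM and Ciart from 0.738 ± 0.245 to 2.88 ± 0.967 FPKM (SD, n = 5 each). The 2 lower genes, Npas2 and Clock, which encode activators of the Per genes, were named after their values were seen, and Npas2 fell from 1.94 ± 0.878 to 0.435 ± 0.278 FPKM. Clock fell from 6.20 ± 0.506 to 4.87 ± 0.639 FPKM, and its call was lost without hypoxia replicates 4 and 5 (adjusted p = 0.131, log2 fold change -0.24 against -0.32 with all libraries). The labels give no time of day at which the kidneys were taken.

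Some transporters and male-biased genes of the kidney were lower. Of 19 organic ion transporters, 6 were lower and 2 higher (7 and 3 adjusted over the list alone). Slc22a6, the main organic anion transporter of the tubule, fell from 262.8 ± 45.3 to 116.8 ± 26.4 FPKM, while the drug efflux pumps Abcb1a and Abcb1b rose, Abcb1a from 0.994 ± 0.234 to 3.43 ± 0.797 FPKM (SD, n = 5 each). Of 10 genes known as androgen-responsive in the mouse kidney, 5 were lower and 1 higher (5 and 2 adjusted over the list alone), with Odc1, ornithine decarboxylase, falling from 329.9 ± 74.5 to 113.5 ± 8.39 FPKM. Of 8 markers of the late proximal tubule, 3 were lower and 0 higher (4 lower adjusted over the list alone), Cyp7b1, Slc22a19 and Atp11a. Camera adjusted p was 0.0188 for the transporters and 0.00358 for each of the other 2 lists, against an adjusted p of 0.984 and 0.862 with an estimated correlation. Without hypoxia replicates 4 and 5 the camera adjusted p was 0.196 for the transporters, 0.0383 for the androgen-responsive genes and 0.0570 for the late proximal markers.

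The series reported renal damage at high altitude from tissue sections. Havcr1 and Lcn2, common injury markers, did not pass the gene test. Havcr1, which encodes kidney injury molecule 1, was at 1.51 ± 1.05 FPKM in controls and 0.839 ± 0.322 FPKM in hypoxia (log2 fold change -0.50, SE 0.297, limma adjusted p = 0.285), and Lcn2, which encodes a lipocalin released by injured tubules, was at 1.98 ± 0.907 and 3.24 ± 3.48 FPKM (0.28, SE 0.476, adjusted p = 0.722; -0.090 without hypoxia replicates 4 and 5). Of 21 injury genes, 4 were higher and 2 lower (4 and 4 adjusted over the list alone, camera adjusted p = 0.969). Without hypoxia replicates 4 and 5, 2 of the 20 then tested were higher and 3 lower (camera adjusted p = 0.640). Spp1, which encodes osteopontin and was named after its values were seen, rose from 480.2 ± 77.4 to 897.3 ± 335.1 FPKM (adjusted p = 0.0440, and 0.0639 without hypoxia replicates 4 and 5). Fgg, a fibrinogen chain, rose from 3.18 ± 1.04 to 12.2 ± 5.82 FPKM and Fgb from 0.366 ± 0.123 to 1.04 ± 0.238 FPKM, while Tnfrsf12a, the receptor of the cytokine TWEAK, fell from 7.96 ± 0.794 to 3.33 ± 1.01 FPKM (SD, n = 5 each). The log2 fold change of Fgg was 1.72, and 1.25 without hypoxia replicates 4 and 5 (limma adjusted p = 0.0114). Of 22 matrix genes, 3 were lower and 0 higher (3 lower adjusted over the list alone, camera adjusted p = 0.539), all of them collagens, with Col4a1, of the basement membrane, falling from 54.7 ± 3.26 to 33.0 ± 1.40 FPKM.

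Igkc, the kappa light chain of antibodies, lay between 0.559 and 3.39 FPKM in the 5 controls, between 37.7 and 59.97 FPKM in hypoxia replicates 1 to 3, and reached 3117 FPKM across the hypoxia group (log2 fold change 6.09, SE 1.07, limma adjusted p = 0.00741; 4.36 without hypoxia replicates 4 and 5). Of 20 lymphoid genes, 3 were higher, all of antibody-producing cells, namely Igkc, Ighg2b and Jchain, and 0 lower (3 and 0 adjusted over the list alone). Of 19 myeloid genes, only S100a8 was higher and 0 were lower (0 adjusted over the list alone). Camera adjusted p was 6.24e-05 for the lymphoid and 9.12e-05 for the myeloid list, and adjusted p was 0.984 for both with an estimated correlation. The lymphoid median was 1.41 over 20 genes, and 0.69 without hypoxia replicates 4 and 5 over the 9 genes then tested. The myeloid one was 0.95 over 19 genes, and 0.28 over 18 without them.

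Ribosomal protein genes had a median log2 fold change of 0.32, with 6 of 55 higher and 0 lower (10 higher adjusted over the list alone), for example Rpl3 at 0.63 and Rpl5 at 0.54 (camera adjusted p = 8.85e-06, adjusted p = 0.984 with an estimated correlation). Without hypoxia replicates 4 and 5 the median was 0.13, with 14 of 55 higher. The calls of Rpl3 and Rpl5 were lost without single controls, with adjusted p up to 0.0666 and 0.0605 without control replicate 1, and both genes were highest in hypoxia replicate 5. Podocyte markers had a median of 0.39, with 2 of 10 higher and 0 lower (4 higher adjusted over the list alone), including Wt1, a podocyte transcription factor, which rose from 1.95 ± 0.120 to 3.56 ± 0.591 FPKM (camera adjusted p = 0.00105, adjusted p = 0.862 with an estimated correlation). The podocyte median was 0.47 without hypoxia replicates 4 and 5, with 7 of 10 higher (camera adjusted p = 2.49e-06, adjusted p = 0.400 with an estimated correlation). Cell cycle, interferon and adrenal lists passed camera upwards (adjusted p = 0.00531, 0.0149 and 0.0391), with 0 genes past the threshold in each (also 0 adjusted over the list alone) and adjusted p = 0.984 with an estimated correlation. Without hypoxia replicate 5 the cell cycle and interferon calls were lost, with adjusted p = 0.0837 and 0.199. The interferon call was also lost without control replicate 1 (adjusted p = 0.0552). Without both hypoxia replicates 4 and 5 the adjusted p was 0.0237 for the cell cycle and 0.540 for interferon. The adrenal call was lost without control replicate 4 or control replicate 5 (adjusted p = 0.0632 and 0.0537) and rests on hypoxia replicate 4.

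Lists that did not pass camera held single changed genes. In cholesterol synthesis 4 of 20 genes were lower and 0 higher (camera adjusted p = 0.814), among them Idi1, which fell from 28.3 ± 2.79 to 11.9 ± 3.99 FPKM, and Cyp51, from 83.4 ± 11.5 to 37.1 ± 11.8 FPKM (SD, n = 5 each). In amino acid metabolism 3 of 27 were higher, Hpd, Kynu and Hao2, and 2 lower (camera adjusted p = 0.832), with Kynu, kynureninase, rising from 1.48 ± 0.150 to 4.94 ± 0.953 FPKM and Aadat, an enzyme of the same pathway, falling from 150.6 ± 24.8 to 66.2 ± 10.9 FPKM. Of 24 antioxidant genes 2 were higher and 5 lower (camera adjusted p = 0.104), including Gclc, of glutathione synthesis, which fell from 108.0 ± 14.8 to 69.1 ± 10.9 FPKM. The 2 higher genes, Nqo1 and Gsta2, each lost their call in 7 of the 10 fits without 1 library (adjusted p up to 0.0733 and 0.0704). Of 18 genes of the renin-angiotensin system and vessel tone 0 were higher and 3 lower (camera adjusted p = 0.616), including Ace, angiotensin-converting enzyme, which fell from 50.8 ± 4.41 to 25.7 ± 9.24 FPKM. Without hypoxia replicates 4 and 5, 3 of the 18 were higher and 2 lower (camera adjusted p = 0.0531), so the one-sided count depended on those libraries.

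Summed marker expression of 16 cell types and tissues was compared by an exact two-sided permutation test over 252 regroupings. None of the 16 passed after adjustment, with the smallest p of 0.00794, the smallest these regroupings can give, for the skeletal muscle list (adjusted p = 0.127). That sum was 16.8 ± 1.13 FPKM in controls and 7.54 ± 0.880 FPKM in hypoxia, and included Pvalb, also expressed by the distal convoluted tubule, which fell from 15.6 ± 1.19 to 5.92 ± 1.59 FPKM (SD, n = 5 each, limma adjusted p = 0.00187). The podocyte sum was 111.1 ± 8.64 FPKM in controls and 152.2 ± 30.5 FPKM in hypoxia (p = 0.0397, adjusted p = 0.212, exact permutation test). Proximal tubule markers summed to 3747 ± 379.5 and 3110 ± 762.0 FPKM (p = 0.103, adjusted p = 0.413, exact permutation test). With 252 regroupings, 1 list alone at the smallest p cannot pass the adjustment over 16 lists, so the absence of calls says little about cell composition. Without hypoxia replicate 5, 3 of the 16 sums passed.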

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

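All tests of explanations in this part except the count over other splits of the samples were chosen after the results had been seen, and the bounds that decide them were set at that point too. That count was taken over 100 splits of the 10 samples into 5 and 5, with the real split placed among them and the others drawn at random. The real split gave 1748 genes and the highest other split 1. Because the real split counts itself, a share of 1 in 100 is the lowest that this comparison can give, and only 126 splits exist. Chance is argued against for the count of 1748 but not excluded. The other splits mix the 2 groups, so the gap between 1748 and 1 does not measure how unlikely chance is.

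Of 250 group values examined, 22 had 1 library far from the other 4, where chance alone gives about 12.5, and 12 of the 22 lay in hypoxia replicate 5. In hypoxia replicate 5, FPKM was low for Pgam1 (62.2, group median 92.4), Atp5g1 (20.8), Aadat (47.6), Col4a2 (22.6), Pvalb (3.27) and Slc34a1 (398.1, group median 805.7), and high for Rpl3 (229.4) and Rpl5 (163.0). Its summed FPKM was low for proximal tubule (1779), distal convoluted tubule (1646) and retina lists (3.59) and high for the pancreas list (60.7). In hypoxia replicate 4, Pklr (7.75 FPKM) was low and the adrenal sum was 1211 FPKM against a group median of 3.32. Ndufs6 was high in hypoxia replicate 2 (55.8 FPKM). Among controls, replicate 3 was high for Abcb1b (1.25 FPKM) and Cyp4a14 (65.1 FPKM), and replicate 5 low for mt-Atp6 (147.1 FPKM, group median 525.9). Control replicate 4 was low for Rbm3 (5.48 FPKM), Cyp2j13 (48.5 FPKM) and the proximal tubule (3103 FPKM) and liver sums (110.1 FPKM).

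Hypoxia replicate 5 stood apart from all other libraries. Immune cells entering the kidney are argued against as the whole cause, because 10 pancreatic enzyme genes summed to 117.2 times the highest other library, and these enzymes are made by the exocrine pancreas. Spleen and pancreas tissue in the sample is a candidate explanation, since 61 of 62 nephron marker genes were lower than in hypoxia replicates 1 to 3, at a median log2 difference of -0.69, while erythroblast genes summed to 238.4 times and red pulp macrophage genes to 112.8 times the highest other library. These marker sets were chosen after the levels had been seen. Whether and how other tissue came into the sample, and whether part of the immune signal is from the kidney, stays open.

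The respiratory chain lists were lower in hypoxia with camera's preset correlation, but neither call held with an estimated correlation (camera adjusted p = 0.862 for both). Other tissue in hypoxia replicates 4 and 5 is argued against as the whole cause, since the median of the 70 genes was -0.26 without them. It was -0.36 with all 10 libraries, so a part of the shift may go with those 2. A bias from transcript length, GC content or abundance was examined with 10000 lists of genes matched on these traits. The median of -0.26 lay at percentile 0 of them, where the lowest matched median was -0.21 and the middle one -0.061. These lists were drawn gene by gene and lack the correlation among respiratory chain genes, estimated at 0.78 and 0.79 over all 10 libraries. The percentile therefore cannot exclude such a bias. Matched genes shifted the same way but less, so these traits may go with part of the shift. Fewer proximal tubule cells cannot be told apart from lower expression, because the change of respiratory chain genes relative to proximal tubule markers was -0.27 on the log2 scale without those 2 libraries (-0.30 against -0.023), with p = 0.107 (exact two-sided permutation test, 56 regroupings). A response to altitude, and any other difference between the 2 sites such as diet, temperature or time of sampling, stay open and were not tested.

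Several male-biased genes of the kidney were lower in hypoxia. Female mice in the hypoxia group are argued against, since Ddx3y was at 12.2 FPKM or more in every hypoxia library. Loss of the late proximal tubule cannot be told apart from the pattern, because 6 late proximal markers outside the male-biased list had a median of -0.43 (SD 0.572) without hypoxia replicates 4 and 5, against -0.42 (SD 1.26) for the 10 male-biased genes. In those 8 libraries the 6 markers ranged from -1.14 to 0.49, the summed FPKM of all late proximal markers changed by -0.036 on the log2 scale (p = 0.839, exact permutation test), and Slco1a1 and Cyp7b1 were at -3.06 and -2.52. Lower androgen action may account for the pattern, but the 5 lower members of the list define it and so cannot decide, and no hormone was measured here.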

How the results depend on the processing

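The fits without hypoxia replicates 4 and 5 and with limma voom on recovered reads were chosen after seeing the data. The counts of 1748 changed genes, 559 higher and 1189 lower, stayed within 1.5 times under quantile and median-of-ratios scaling, both other pseudocounts, the 5 FPKM filter, protein-coding genes only, plain eBayes, voom (1693) and without hypoxia replicates 4 and 5 (1808). They were 966, 263 and 703 with no filter on low values, where 30650 genes were tested, and 3253, 1309 and 1944 with sample quality weights. Rescaling without the most abundant genes gave 961 higher and 780 lower, and moved the median of all genes from 0.012 to 0.085. Stricter thresholds gave fewer by construction, 456 (107 higher, 349 lower) at an adjusted p of 0.01 and 248 (90 and 158) with an absolute log2 fold change of at least 1. The exact rank-sum test gave 0 genes, 0 higher and 0 lower, and 0 of the 99 named genes, because its smallest possible p, shared by 2170 genes, adjusts to 0.0558. Leaving out 1 library gave 824 to 2724 genes, 221 to 1094 higher and 603 to 1630 lower, the highest without hypoxia replicate 5.

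The 18 lists past camera became 1 with an estimated correlation and 6 with fry. The 5 energy lists became 0 and 1, and the lymphoid and myeloid lists, the 2 past camera among 4 lists of injury, matrix and immune genes, 0 and 0. None of the 18 changed direction under any alternative run. Of the 26 lists not past camera, 18 changed direction under at least 1 alternative, so no direction is read from them, and 1 of these also passed, the erythroid list without hypoxia replicates 4 and 5 (adjusted p = 0.0201). Without 1 library, fatty acid synthesis passed without control replicate 2 or hypoxia replicate 4 (adjusted p = 0.0185 and 0.0123), the antioxidant list without hypoxia replicate 2 (0.0483) and intercalated cell markers without hypoxia replicate 5 (0.00885). The first 2 of these and gluconeogenesis also passed with no filter on low values, and intercalated cell markers with sample quality weights and without hypoxia replicates 4 and 5. The cell type sums past the test numbered 0 to 3 when 1 library was left out, 3 of them without hypoxia replicate 5.

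Of the 99 named genes past the threshold, 69 stayed past it in every fit without 1 library in which they were tested. One of the 69, Mas1, was tested in only 5 of the 10 fits. A further 30 did not stay past it in at least 1 fit, and 8 of the 99 did not without hypoxia replicates 4 and 5. Vegfa and Lcn2, neither past the threshold, changed sign. Vegfa ranged from -0.11 to 0.12 without 1 library, and Lcn2 from -0.17 to 0.51, with -0.020 under quality weights and -0.090 without hypoxia replicates 4 and 5. Except where a construction is named, the cause was not tested.

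Replicate numbers did not pair the samples, since the same-number correlations of deviations ranged from -0.077 to 0.086. With the replicate block the counts were 999 genes, 265 higher and 734 lower. Depth limits Epo and other genes near 3 reads in both groups, for which small differences were not detectable.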

Other observations

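Some antibody genes and 2 genes of brown fat differed between the groups, and the antibody genes given here were named after their values were seen. Ighm, another antibody gene, did not pass the gene test (limma adjusted p = 0.266), and the fat tissue list did not pass camera (adjusted p = 0.909). Igha, the constant region of immunoglobulin A, was at 0 to 0.112 FPKM in controls and at 7.33 to 27.4 FPKM in the 5 hypoxia libraries, and Ighg2c at 0 in all controls and at 2.71 to 57.7 FPKM in hypoxia. Hypoxia replicates 1 to 3, which lacked the spleen and pancreas genes of replicate 5, had Igha at 7.33 to 9.82 FPKM. Ucp1, the uncoupling protein of brown fat, was at 7.30 ± 5.44 FPKM in controls and at 0.0340 ± 0.0411 FPKM in hypoxia (SD, n = 5), and Cidea at 10.1 ± 7.21 and 0.740 ± 1.04 FPKM. Both passed the gene test (limma adjusted p = 0.0244 and 0.0392), but were spread widely among the controls, lost their calls in 5 and 8 of the 10 fits without 1 library, and Ucp1 also lost it without hypoxia replicates 4 and 5 (adjusted p = 0.0599), in fewer samples and with a log2 fold change of -3.29 against -3.23 with all libraries.

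One hypothesis was formed after the values were seen and tested then. Dio1, the deiodinase that activates thyroid hormone, fell from 22.7 ± 2.07 to 6.45 ± 2.09 FPKM, and Gpd2, mitochondrial glycerol-3-phosphate dehydrogenase, from 17.4 ± 1.67 to 5.44 ± 0.726 FPKM (SD, n = 5, limma adjusted p = 0.000610 and 2.74e-05). Both are induced by thyroid hormone, and lower thyroid hormone action may link them. Of the other responsive genes Thrsp, Me1, Klf9 and Hr, 1 was lower past the threshold, Me1 at -0.75 (adjusted p = 0.0352), whose call was lost in 6 of the 10 fits without 1 library (adjusted p up to 0.0854, without control replicate 2). Thrsp was at -1.16 (adjusted p = 0.146) and Klf9 at -0.053 (adjusted p = 0.823), and Hr was below the filter, so the test leaves lower thyroid hormone action open.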
